A study of Bos grunniens with 36 samples.

How the data were processed

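Mammary gland biopsies of 4 yaks (Bos grunniens) at 9 times between day -30 and day +240 around calving (30 and 15 days before it, and at day +1, +15, +30, +60, +120, +180 and +240 from it) were measured on 36 single-colour arrays with 4 arrays to a slide, a cattle design used on yak RNA. Per the labels the left and the right rear udder gland were biopsied in alternation, which the files do not record array by array, so that the side was not a term of any fit. Animals are numbered 1 to 4 as in the sample names, and the same number is the same animal at each day.

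The authors' scanner software, Feature Extraction 10.7.3.1, made 1 file per array, and the deposited files give for each spot a processed signal in intensity units, with the local background subtracted and spatial trends removed but not normalized between arrays, the raw signal and background intensity, and quality marks of another unit, 0 or 1, for spots well above background, saturated or out of line. The authors also deposited a table of normalized log2 values, made per the labels with GeneSpring 12 by setting the 75th percentile of each array to 0, and per the labels tested with JMP Genomics 7 in a mixed model with time as main effect and animal as random. That table holds 34997 of the 43653 probes. Each of its 36 columns was compared with all 36 scanner files over the probes they share, by Pearson's r across probes, which are not independent replicates, and by the spread of the difference. For that r, spots left out as out of line were given the mean of their probe, which keeps it under 1. Over the probes with a value in both, each column equals 1 scanner file less a constant (the standard deviation of the difference rounds to 0 in all 36), which lies within 0.008 of the 75th percentile of that file. The file so matched is deposited under another sample for all 36 columns. The scanner files' own record was kept as the main one, since design and grouping follow the samples under which those files are deposited, and the whole table with its own record was an alternative set before the data were examined. Putting the table's record on the scanner values of all probes was added after both records had been seen.

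From the scanner files, control spots and spots marked as out of line were left out (10 to 151 spots an array), spots of a probe were averaged, and the log2 of the processed signal less the 75th percentile of the array was used. The files mark 0 spots as saturated on any of the arrays. A probe was kept when its spots were well above background on at least 3 of the 4 arrays of at least 1 day, and 1 probe stood for each gene symbol, that with the highest mean. This left 21559 genes or unnamed transcripts, 20106 of them also in the table. Symbols come from the annotation in the files, 15008 in all, of which 12983 are also symbols of the yak gene table. Probe positions are those the file headers give on the cattle assembly UMD 3.1. Of the genes with several probes, 15 had probes called opposite ways at day +30.

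Differences between days were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, and the data.table package at version 1.17.8), with time as fixed effect and animal as a random block, whose consensus correlation was 0.0377. The tests are two-sided, adjusted by Benjamini-Hochberg within each of 15 comparisons, 8 with day -30 and 7 between neighbouring days, and called at an adjusted p under 0.05, and an F test covers all days. The pairing by animal was checked on the values: deviations from the day mean had a mean r of 0.125 between arrays of the same animal and of -0.0418 between others, and for 29 of 36 arrays the best match at another day was the same animal. Each animal had the same position on the slide at every day, and animal 1 always lay on another slide than the rest of its day. The check therefore cannot tell the animal from position or slide. The same code was tested on simulated data with the gene means and spreads of these arrays, where of 100 genes given a log2 change of 1 it recovered 26, of 100 given a change of 2 it recovered 66, and it called 7 unchanged genes. There genes varied independently with 1 spread at all days, without effects of slide or brightness and with the right days. The simulation thus does not show how many false calls the real arrays give. A comparison of 4 arrays with 4 can give 35 splits. A change is written as a difference of log2 means with its standard error. That error rests on 1 estimate of the spread per gene over all 36 arrays, not on the arrays of the compared days alone. The spread differed between days, as for CSN1S1, with a standard deviation of 0.2 at day +1 and 4.45 at day +180. Where a gene was above background on no array of a group, its fold is a bound against the background of those arrays. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3).

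Before the data were examined, 30 gene lists were fixed for this tissue: milk proteins, fatty acid uptake and activation, fatty acid synthesis and desaturation, triacylglycerol synthesis and milk fat globule, lipogenic regulators, cholesterol synthesis, glucose uptake and lactose synthesis, amino acid transporters, lactogenic hormone signalling, mTOR signalling, cytosolic ribosomal proteins, unfolded protein response, oxidative phosphorylation, cell division, involution and acute phase, antibody transfer and mucosal defence, interferon response, MHC class II, luminal epithelial, myoepithelial, fibroblast and matrix, adipocyte, endothelial, T and NK cell, B and plasma cell, macrophage, neutrophil and skeletal muscle markers, blood cell haemoglobin, and immediate early and stress genes. Several members of the marker lists are also expressed by mammary epithelium. The shift of each list in each comparison was tested with camera (cameraPR, preset correlation 0.01), adjusted over all 450 tests together, of which 152 passed. With a correlation estimated from the data 0 of these passed (lowest adjusted p = 0.38), and each call is given with that adjusted p. Counts of members come from the tests of single genes, and beside them stand the counts adjusted over the list alone.

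Genes are named by a rule set before the data were examined: among genes with a symbol, an adjusted p under 0.05 and the same direction in all 4 animals, the 5 largest rises and 5 largest falls, or 10 and 10 for day +1, +60 and +240 against day -30 and for day +240 against day +180, up to 4 members of each list with the smallest adjusted p, the 10 genes with the largest F, and a fixed panel of milk synthesis and tissue genes. For the largest rises and falls, a signal above background on at least 1 array of both days was also required, which that rule did not hold. The panel genes MKI67 and TOP2A are not on the array under these names. The text gives a selection of the genes so named.

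Each result was computed again with quantile normalization, a normexp background correction (offset 50), no filter on dim probes, the mean of all probes of a gene, the animal as a fixed effect, no block, an ordinary ANOVA, slide as a random and as a fixed block, the 8 arrays of the compared days alone, the deposited table, and without each animal in turn. Fits without 2 arrays low in milk protein mRNA, and a fit with the brightness of the array (log2 of its 75th percentile) as a covariate, were added after seeing the data. In the scanner record each slide holds 3 arrays of 1 day and 1 array of another, and in the table's record it holds 1 day, so that there slide and day cannot be told apart. The 1 array of another day is always that of animal 1. Without animal 1 slide and day can therefore not be told apart in the scanner record either. The closing section gives the effect of each. Raw images and sequence were not analysed here.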

Results

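Mammary gland tissue of 4 yaks was sampled at 9 times around calving, from day -30 to day +240. The RNA of each biopsy was put on 1 array of a cattle gene expression design, which gave 36 arrays and 4 arrays a day. The series follows the gland from late pregnancy through a whole lactation, with day -30 as the reference. The brightness of the arrays, as the 75th percentile of the signal, ran from 1029 to 6450 intensity units. Between 68.6% and 89.3% of the spots lay well above the local background. By day, the mean share of such spots ran from 73.5% at day +30 to 85.2% at day -30. At day +1, +30, +60 and +180 every array was dimmer than every array of day -30 (4853 to 5725 units at day -30, 1779 to 2114, 1278 to 2512, 1178 to 2619 and 1273 to 4357 at those days), so that day and brightness go together there. A fit with brightness as a covariate cannot tell them apart at those days. Changes of genes that were above background on fewer than 3 of the 4 arrays of a day rest on values at the floor of the array, and such genes are pointed out. The number of arrays limits the precision of every value. The tests covered 21559 genes or unnamed transcripts.

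The deposited files hold 2 records of which array belongs to which day and animal, and these contradict each other. Each of the 36 columns of the deposited table of normalized values matched exactly 1 scanner file (Pearson's r across probes at least 0.999, where r with the file of its own label lay between 0.871 and 0.982). For 0 of the 36 columns was that file the one deposited under the same sample. The day was the same in both records for 9 arrays and differed for 27. Values below follow the scanner files, and each comparison gives the count of genes by the table's record beside them, with the named genes that did not pass in it. The overlaps given as by chance are those of 2 independent lists. Both records hold the same 36 arrays, and 9 have the same day in both, so that the lists are not independent. An overlap above that number is therefore no evidence that either record is right. Along the slides, the scanner record was the table's record displaced by 3 arrays, so that in the table each slide held all arrays of 1 day.

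**Figure D1:**
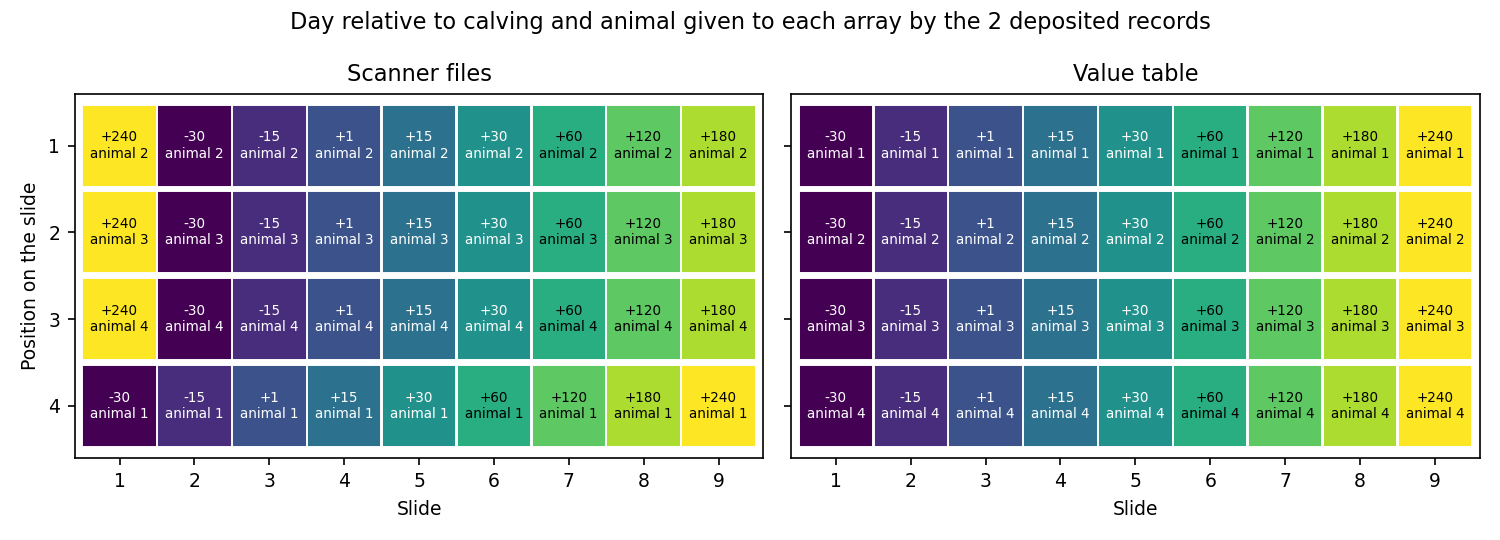
Day relative to calving and animal of each array on the 9 slides (columns) and 4 positions (rows), as the scanner files (left) and the table of normalized values (right) give them, with colour for the day. The 9 arrays at position 4 carry the same day in both and the other 27 do not.

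Over the whole course, 4660 of the 21559 genes changed (limma F test, adjusted p under 0.05). The 10 genes with the largest F included 6 with known roles in cell division: KIF23, KIF20A, PRR11, DLGAP5, CDC20 and ASPM, with adjusted p between 3e-08 and 1.44e-06. KIF20A, a mitotic kinesin, had its highest mean at day +240 (-2.07), on a log2 scale where 0 is the 75th percentile of the array, and was above background on 0 to 2 of 4 arrays at each day from day +30 to day +180. The same held for PRR11 (0 or 1), ASPM (0 or 1) and DLGAP5 (1 or 2) at these 4 days. The others were TM4SF18, a membrane protein, with an adjusted p of 1.59e-08, ELP, and the transcriptional regulators HES2 and MACC1. Of the milk synthesis genes followed by name, SLC2A1, the glucose transporter of the mammary epithelium, passed at an adjusted p of 0.00821. INSIG1, which restrains sterol synthesis, passed at 0.0183, THRSP, a lipogenic regulator, at 0.0376, LPL, which releases fatty acids from plasma lipid, at 0.041, and SCD, the stearoyl desaturase, at 0.0464. None of these 5 passed with slide as a random or a fixed block (0.0629 to 0.861), with the brightness of the array as a covariate, chosen after seeing the data (0.0562 to 0.412), or without animal 2 or animal 3. With normexp SLC2A1 alone of the 5 passed, and without animal 4 INSIG1 alone did. Among all 37 genes followed in the F test, which include the 10 with the largest F, 9 calls were lost with slide as a fixed block and 5 with normexp. That is more than these milk synthesis genes account for. THRSP, LPL and SCD were lost without a block (0.0542, 0.0501 and 0.0543), and LPL and SCD in an ordinary linear model of each gene with the animal as a factor (0.0707 and 0.088). Single calls were lost for LPL without animal 1 (0.0577), for THRSP with the mean of all probes (0.0587), and for SCD with quantile normalization (0.0639) and with the animal as a fixed effect (0.0584). The caseins CSN1S1, CSN2 and CSN3 did not (adjusted p = 0.415, 0.312 and 0.0643), and neither did LALBA of lactose synthesis (0.341) or the whey protein PAEP (0.362). On 2 arrays, of animal 1 at day +120 and day +180, milk protein mRNA was low (list means -1.3 and -1.23, against 2.73 in this animal at day -30). Without these arrays, a choice made after seeing the data, 7623 genes passed. Then CSN1S1, CSN2, CSN3, LALBA and PAEP passed at adjusted p = 0.0153, 0.00359, 0.000682, 0.0355 and 0.00368. All 5 also passed without animal 1, where slide and day cannot be told apart. CSN1S1, CSN2, CSN3 and PAEP did with slide as a fixed block (0.0136, 0.00854, 0.00834 and 0.00167). By the table's record 8502 genes changed, 4060 of them in both, and of these 5 genes CSN3 passed (0.0125). With slide as a random block 1322 genes passed and with slide as a fixed block 61. Without animals 1, 2, 3 and 4 in turn 6780, 652, 820 and 506 did, the first of these with each day on 1 slide of its own.

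**Figure D2:**
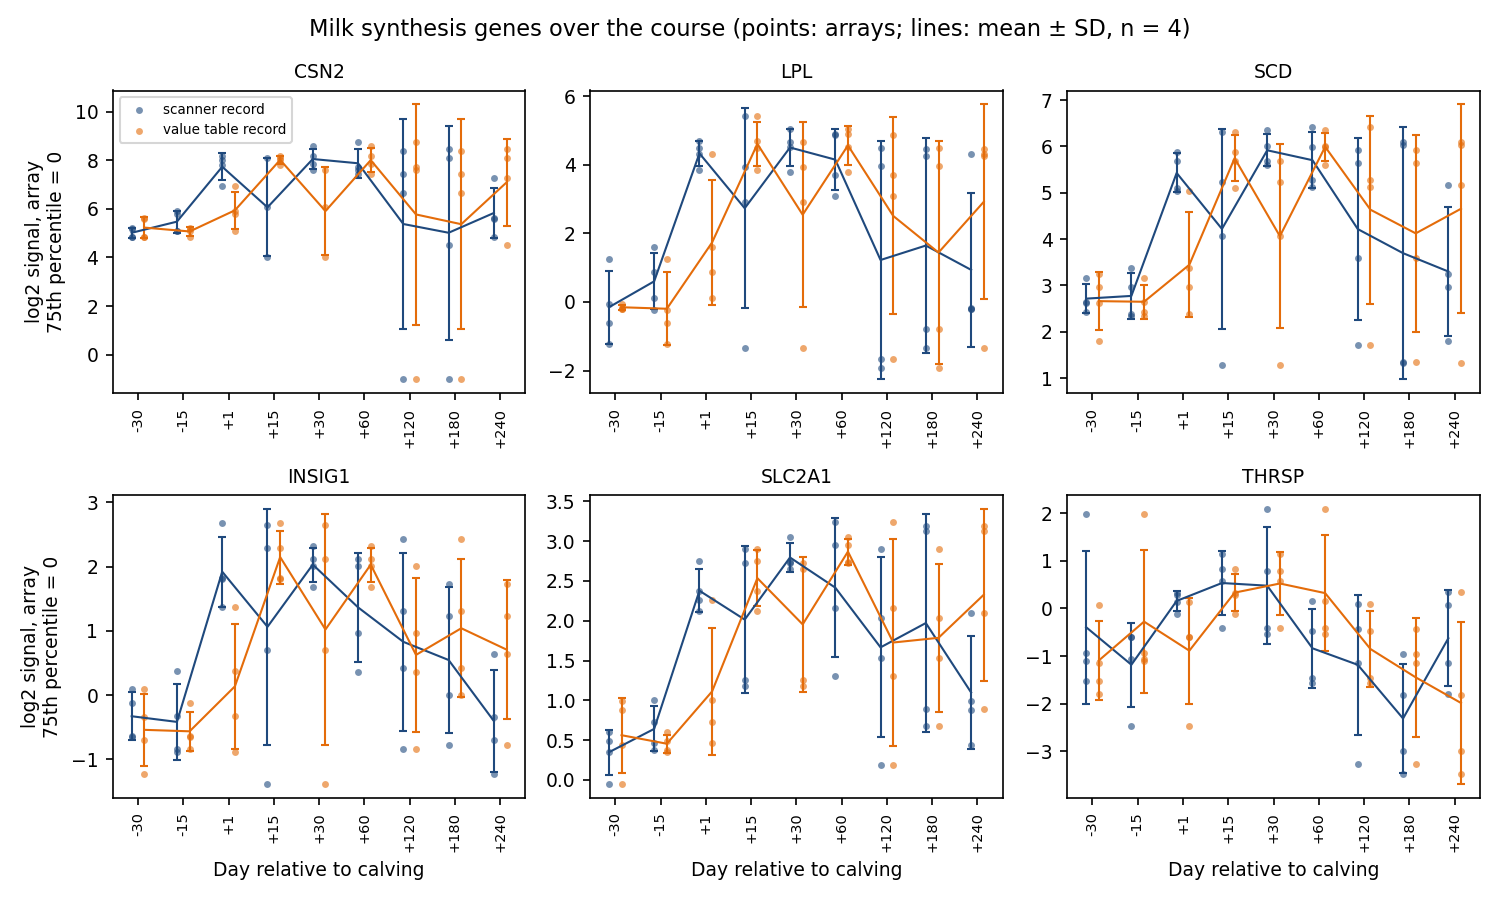
Signal of 6 milk synthesis genes (vertical axes, log2 with the 75th percentile of the array at 0) by day relative to calving (horizontal axes), for each array (points) and as mean ± SD of the 4 arrays of a day (lines, 3 arrays for CSN2 at day +15 by the scanner record), by the scanner record (blue) and the table's record (orange). CSN2 lies far below its other values on 1 array at day +120 and 1 at day +180, and its mean in the scanner record runs from 5.02 at day -30 to 8.05 at day +30.

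Between day -30 and day -15, still in pregnancy, 0 genes passed with limma, while 1624 had an unadjusted p under 0.05 and 1740 did in an ordinary linear model of each gene with the animal as a factor. By chance alone a share of 0.05 of the 21559 genes tested would have such a p, and both counts are above it. Cell division genes had a median log2 change of -1.06, with 0 of 32 members passing and 8 lower adjusted over the list alone (camera adjusted p = 4.53e-17, adjusted p = 0.73 with an estimated correlation). Myoepithelial markers, of the contractile cells around the alveoli, had a median change of 0.44 with 0 of 14 passing and 1 higher adjusted over the list alone (camera adjusted p = 9.85e-06, adjusted p = 0.38 with an estimated correlation). Milk proteins had a median change of 0.75 with 0 of 8 passing (camera adjusted p = 0.0409, adjusted p = 0.764 with an estimated correlation). By the table's record 1 gene fell, the median of the cell division list was -0.21 and that of the myoepithelial markers -0.01. Without animal 1, 209 genes passed, and a fit of the 8 arrays of both days alone called 71.

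At day +1, at the onset of lactation, 305 genes differed from day -30, 152 higher and 153 lower. LPO, lactoperoxidase, an antibacterial enzyme of milk (probe for NM_173933, cattle assembly UMD 3.1, chromosome 19, 9471396 to 9471455), rose by 9.60 ± 2.17 on the log2 scale (SE, n = 4 arrays a day, adjusted p = 0.0259, higher in 4 of 4 animals), from a mean of -6.02 to 3.58. ALOX15, an arachidonate lipoxygenase, rose by 6.70 and BDH1, of ketone body metabolism, by 6.21. ATP2B2, the calcium pump that delivers calcium to milk, rose by 5.26 (above background on 1 of 4 arrays at day -30) and PTHLH, the parathyroid hormone related protein, by 5.17. RSPO1, a secreted enhancer of Wnt signalling (mean 2.46 at day -30 and -3.57 at day +1), had a log2 change of -6.03 ± 1.02 and the dynein component DNALI1 of -4.99. Of the milk proteins 1 of 8 rose, LPO (3 adjusted over the list alone, camera adjusted p = 0.000359, adjusted p = 0.73 with an estimated correlation). Fatty acid uptake and activation had 1 of 15 higher, ACSS1, which activates acetate, at 2.10 ± 0.51, while LPL differed by 4.49 ± 1.37 without passing (adjusted p = 0.0712). Adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.00499, adjusted p = 0.73 with an estimated correlation). Of the lipogenic regulators 2 of 13 rose, PPARA (1.27) and PPARGC1A (2.51), both transcriptional regulators of fatty acid oxidation. In this list 7 did adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.73 with an estimated correlation). Triacylglycerol synthesis and milk fat globule genes had 0 of 17 and cholesterol synthesis genes 0 of 21 passing, against 8 and 7 higher adjusted over the list alone (camera adjusted p = 0.000128 and 0.000114, adjusted p = 0.73 with an estimated correlation in both). In cell division 1 of 32 fell, the replication helicase subunit MCM7 (-1.35), and 7 were lower adjusted over the list alone (camera adjusted p = 1.84e-06, adjusted p = 0.73 with an estimated correlation). By the table's record 1255 genes passed, 94 of them in both and the same way, 27 higher and 67 lower (2.70 and 4.69 by chance). In it BDH1 (3.25), ATP2B2 (2.39), PTHLH (1.58) and PPARA (0.53) did not pass. Slide as a random or as a fixed block left 0 genes (and MCM7 turned to 0.11 with the fixed block). Brightness as a covariate also left 0, and with it the list calls of this paragraph were lost. Without animals 1, 2, 3 and 4 in turn 883, 0, 0 and 0 passed, without the 2 arrays low in milk protein mRNA 1483, and in a fit of the 8 arrays of both days alone 7416. In the fit to all arrays 49.8% of the calls were higher, or 68.9% with the normexp background correction.

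At day +15, 313 genes differed from day -30, 124 higher and 189 lower. LPO was 8.19 ± 2.17 higher (SE, n = 4, adjusted p = 0.0489), CDH16, a kidney type cadherin, 6.05 ± 1.39 and RRAD, a small GTPase, 5.08 ± 1.01. RSPO1 had a log2 change of -6.46 ± 1.02 and DUSP9, a phosphatase of MAP kinases, of -5.01 ± 0.91. Cell division had 5 of 32 members lower, and 27 adjusted over the list alone, with a median of -1.56 (camera adjusted p = 8.59e-21, adjusted p = 0.73 with an estimated correlation). KIF20A fell by 2.33, CDC20 by 1.95 and TPX2, a spindle assembly factor, by 1.30. Of the neutrophil markers 1 of 10 rose, the cathelicidin CATHL2 (2.04), and 1 fell, the peptidoglycan recognition protein PGLYRP1 (-2.23). Adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.000128, adjusted p = 0.73 with an estimated correlation). Of the antibody transfer and mucosal defence genes 1 of 12 rose, CD14, a receptor for bacterial lipopolysaccharide (3.01), and 2 adjusted over the list alone (camera adjusted p = 0.00527, adjusted p = 0.73 with an estimated correlation). In the milk proteins 1 of 8 passed, LPO (camera adjusted p = 0.0139, adjusted p = 0.748 with an estimated correlation). In cholesterol synthesis 1 of 21 passed, the sterol reductase TM7SF2 at 2.77 (camera adjusted p = 0.00021, adjusted p = 0.73 with an estimated correlation). The table's record called 3609 genes, 213 of them in both and the same way, 86 higher and 127 lower (11.8 and 11.7 by chance), with each gene named here among them. Slide as a random block left 7 genes and as a fixed block 4 (with the median of the mucosal defence list turned to -0.33, and that of the neutrophil list at 0.21, where the direction of the test alone turned). Leaving out animals 1, 2, 3 and 4 in turn gave 234, 0, 3 and 1. Brightness as a covariate gave 121, with the milk protein and cholesterol synthesis calls lost, the 8 arrays of both days alone gave 675, and leaving out the 2 arrays low in milk protein mRNA 633. In the fit to all arrays 39.6% of the calls were higher, or 50.5% with normexp.

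Day +30 differed from day -30 in 4075 genes, 1885 higher and 2190 lower. With the brightness of the array as a covariate 271 passed. LPO was 10.31 ± 2.17 higher (SE, n = 4, adjusted p = 0.0026, in 4 of 4 animals), CRISP3, a secreted protein of exocrine glands, 7.81 ± 1.59 and PNPLA3, a lipid droplet enzyme, 7.70 ± 1.7 (above background on 2 of 4 arrays at day -30). RSPO1, above background on 2 of 4 arrays at day +30, had a log2 change of -7.46 ± 1.02, the neurofilament gene NEF3 of -5.41 and CHRDL2, a chordin-like inhibitor of bone morphogenetic proteins, of -5.01. Of the milk proteins 3 of 8 rose: LPO, CSN3, kappa casein (3.03 ± 0.918, higher in 3 of the 3 animals with a value), and CSN1S2 (4.85), both of the casein micelle (3 adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.73 with an estimated correlation). In fatty acid uptake and activation 6 of 15 rose and 1 fell (8 and 1 adjusted over the list alone). Among them were LPL (4.66 ± 1.37, adjusted p = 0.0196), FABP3, which carries fatty acids in the cell (4.35), VLDLR (2.79) and CD36 (2.55), both of lipid uptake (camera adjusted p = 0.00701, adjusted p = 0.73 with an estimated correlation). Triacylglycerol synthesis and milk fat globule genes had 8 of 17 higher (9 adjusted over the list alone), such as AGPAT6, which starts glycerolipid synthesis (2.71), LPIN1 (5.21), MFGE8 (3.62) and XDH, of the fat globule membrane (2.10). Their median was 2.1 (camera adjusted p = 4.55e-05, adjusted p = 0.73 with an estimated correlation). Cholesterol synthesis had 14 of 21 higher (15 adjusted over the list alone), such as TM7SF2 (3.59), PMVK (2.97), CYP51A1 (2.16) and IDI1 (2.24). The median of the list was 1.61 (camera adjusted p = 1.85e-08, adjusted p = 0.73 with an estimated correlation). Of the lipogenic regulators 6 of 13 rose, also adjusted over the list alone, PPARA (1.51), PPARGC1A (2.62), PPARD (0.85) and INSIG1 (2.36) among them (camera adjusted p = 0.00116, adjusted p = 0.73 with an estimated correlation). In glucose uptake and lactose synthesis 3 of 11 rose and 1 fell (6 and 1 adjusted over the list alone). SLC2A1 stood at 2.45 ± 0.53 (adjusted p = 0.00318), UGP2, which makes UDP-glucose, at 2.15 and the UDP-galactose transporter SLC35A2 at 1.43 (camera adjusted p = 0.0167, adjusted p = 0.73 with an estimated correlation). SCD rose by 3.20 and ELF5, a transcription factor of alveolar cells, by 1.80. By the table's record LPO, CRISP3, RSPO1, CHRDL2, VLDLR, TM7SF2, PPARA and PPARGC1A passed and the other genes named in this paragraph did not. With brightness as a covariate cholesterol synthesis was the only list of this paragraph with a call, each of its milk synthesis genes named here lost its own, and CSN1S2, XDH, SCD and ELF5 turned (-0.10, -0.20, -0.02 and -0.32). Every array of day +30 was dimmer than every array of day -30, so that these losses do not tell brightness from the day. The slope of the covariate rests on differences within days. It was not fitted without the 2 arrays low in milk protein mRNA, each the brightest of its day.

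Also at day +30, cell division fell as a list, with 29 of 32 members lower and 29 adjusted over the list alone, and a median of -2.81 (camera adjusted p = 7.42e-28, adjusted p = 0.73 with an estimated correlation). KIF20A had a log2 change of -3.99 ± 0.445 (SE, n = 4, adjusted p = 6.52e-06, lower in 4 of 4 animals, above background on 1 of 4 arrays at day +30), CDC20 of -3.06, TPX2 of -1.91 and CENPF, a kinetochore protein, of -4.29. The unfolded protein response, the control of protein folding in the secretory pathway, had 13 of 19 genes higher (15 adjusted over the list alone), such as XBP1 (1.39), ATF4 (1.82), DNAJB11 (1.27) and MANF (1.19) (camera adjusted p = 8.39e-09, adjusted p = 0.73 with an estimated correlation). Of the cytosolic ribosomal proteins 72 of 83 were higher and 2 lower (79 and 2 adjusted over the list alone). Their median of 1.13 turned to -0.12 under quantile normalization, so that no direction is given for them (camera adjusted p = 1.59e-23, adjusted p = 0.73 with an estimated correlation). Oxidative phosphorylation had 39 of 78 genes higher (56 adjusted over the list alone), such as ATP5J (0.97), with a median of 0.74 (camera adjusted p = 2.76e-17, adjusted p = 0.73 with an estimated correlation). Of the interferon response genes 8 of 20 fell and 1 rose (12 and 2 adjusted over the list alone). The chemokine CXCL10 stood at -2.72, the RNA sensor DDX58 at -1.17 and the antiviral RSAD2 at -1.61 (camera adjusted p = 0.000834, adjusted p = 0.73 with an estimated correlation). Of the MHC class II genes 5 of 14 fell, also adjusted over the list alone, with CIITA, their transactivator, at -1.45 and BOLA-DOB at -1.75 (camera adjusted p = 0.0174, adjusted p = 0.73 with an estimated correlation). Of the T and NK cell markers 9 of 23 fell (12 adjusted over the list alone), with CD27 at -1.91, CD2 at -1.37 and CD8A at -1.90 (camera adjusted p = 0.000447, adjusted p = 0.73 with an estimated correlation). The record of the table called 1282 genes, 852 of them in both and the same way, 278 higher and 574 lower (39.3 and 83.4 by chance). Among these lists it called 12 of 31 cell division genes lower, 1 of 21 cholesterol synthesis genes higher and 0 of 23 T and NK cell markers. Of the genes named in this paragraph KIF20A, CDC20, TPX2, DNAJB11, CXCL10 and CIITA passed in it and the others did not. With slide as a random block 2033 genes passed and as a fixed block 500 (with CHRDL2 turned to 1.07), and without animals 2, 3 and 4 in turn 1427, 1170 and 550. The 8 arrays of both days alone gave 7415. With brightness as a covariate cell division and the unfolded protein response were the lists of this paragraph that passed, and the calls of KIF20A, CDC20, TPX2 and CENPF held. With that covariate 33 genes were higher and 238 lower. Without it 46.3% of the calls were higher, or 89.7% of 6534 with normexp, which moved the median of all genes to 0.44 in this comparison and to between 0.11 and 0.24 at the other days after calving against day -30.

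The other lists of day +30 were called by camera only for the neutrophil markers. Of these 4 of 10 rose and 1 fell, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.045, adjusted p = 0.73 with an estimated correlation). Fatty acid synthesis and desaturation had 3 of 13 higher, and 4 adjusted over the list alone, with a median of -0.01 and a mean of 0.69, and its camera direction was up (adjusted p = 0.126). Of the amino acid transporters 4 of 16 rose and 1 fell (7 and 2 adjusted over the list alone). In lactogenic hormone signalling 1 of 18 rose (0 adjusted over the list alone), in mTOR signalling 2 of 14 rose and 1 fell, and in involution and acute phase genes 3 of 25 rose and 1 fell. Antibody transfer and mucosal defence genes had 3 of 12 higher and 1 lower, adipocyte markers 3 of 14 higher and 1 lower, myoepithelial markers 2 of 14 higher and 1 lower (6 and 2 adjusted over the list alone). Luminal epithelial markers had 2 of 15 higher and 1 lower. Of the B and plasma cell markers 2 of 12 fell (4 adjusted over the list alone), of the skeletal muscle markers 2 of 12, and of the haemoglobin genes of blood cells 1 of 7. Macrophage markers had 1 of 14 higher, immediate early and stress genes 3 of 22 higher and 3 lower (4 and 3 adjusted over the list alone). Fibroblast and matrix markers had 0 of 20 and endothelial markers 0 of 14 passing. For the lists of this paragraph without a second count it was the same adjusted over the list alone.

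At day +60, 1821 genes differed from day -30, 861 higher and 960 lower. LPO was 9.93 ± 2.17 higher (SE, n = 4, adjusted p = 0.00527), CRISP3 8.0 ± 1.59, and PCP4, a calmodulin regulator, 6.01 ± 1.54. ALOX15 was 5.80 ± 1.43 higher, ATP2B2 5.56 ± 0.97 and PTHLH 5.42 ± 0.953, each of these 6 genes in 4 of 4 animals (ATP2B2 above background on 1 of 4 arrays at day -30). Of the milk proteins 2 of 8 rose, LPO and CSN3 (2.84), and 3 adjusted over the list alone (camera adjusted p = 0.000998, adjusted p = 0.73 with an estimated correlation). LPL was 4.31 and SLC2A1 2.07 higher (adjusted p = 0.0467 and 0.0162). Triacylglycerol synthesis and milk fat globule genes had 4 of 17 higher, AGPAT6 (2.57), MFGE8 (3.33), CIDEA, of the lipid droplet (3.45), and LPIN1 (3.79), and 8 adjusted over the list alone (camera adjusted p = 0.00122, adjusted p = 0.73 with an estimated correlation). Cholesterol synthesis had 7 of 21 higher, such as TM7SF2 (3.69), PMVK (2.92) and FDFT1, squalene synthase (1.01). Adjusted over the list alone 12 were higher and 1 lower (camera adjusted p = 2.2e-06, adjusted p = 0.73 with an estimated correlation). The unfolded protein response had 2 of 19 higher, the ubiquitin ligase SYVN1 (1.55) and the chaperone DNAJB9 (0.95), and 12 adjusted over the list alone (camera adjusted p = 4.13e-06, adjusted p = 0.73 with an estimated correlation). In cell division 28 of 32 fell (29 adjusted over the list alone), with a median of -3.01 (camera adjusted p = 1.55e-41, adjusted p = 0.38 with an estimated correlation). DLGAP5 had a log2 change of -5.37 ± 0.734, the cyclins CCNB1 and CCNA2 of -5.01 and -4.86. At day +60 DLGAP5 and CCNA2 were above background on 1 of 4 arrays, so that their changes are not measured sizes, and KIF20A was above background on 0 of 4 arrays at this day and on 4 at day -30. Of the interferon response genes 4 of 20 fell, among them RSAD2 (-1.69), CXCL10 (-2.22) and IFIH1 (-0.88). In that list 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000418, adjusted p = 0.73 with an estimated correlation). The table's record called 5889 genes, 1379 of them in both and the same way, 660 higher and 719 lower (106 and 140.1 by chance), with 28 of 31 cell division genes lower. Of the genes named here FDFT1 alone did not pass in it. Slide as a random block left 1076 genes, and omitting animals 2, 3 and 4 in turn 449, 385 and 404. With brightness as a covariate 282 passed, 68 higher and 214 lower, cell division alone of these lists kept a call, and the median of the triacylglycerol synthesis and milk fat globule list turned to -0.25. The 8 arrays of both days alone gave 2792, and leaving out the 2 arrays low in milk protein mRNA 3235. In the fit to all arrays 47.3% of the calls were higher, or 58.8% with normexp.

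At day +120, 2124 genes differed from day -30, 859 higher and 1265 lower. PTHLH was 4.75 ± 0.953 higher (SE, n = 4, adjusted p = 0.00262), RRAD 4.59 ± 1.01 and CA4, a carbonic anhydrase, 4.01 ± 1.08. ELP had a log2 change of -7.68 ± 0.975, the ribonuclease RNASE3 of -6.66 ± 1.56 (above background on 2 of 4 arrays at day +120) and RSPO1 of -6.45 ± 1.02. In cell division 23 of 32 fell (25 adjusted over the list alone), with a median of -2.39, DLGAP5 at -5.24 (above background on 1 of 4 arrays at day +120) and NUSAP1, a spindle protein, at -2.74 (camera adjusted p = 7.58e-25, adjusted p = 0.73 with an estimated correlation). Of the endothelial markers 7 of 14 rose, such as VWF (1.36), EGFL7 (1.19), CLDN5 (1.23) and ENG (0.89), and 8 adjusted over the list alone (camera adjusted p = 0.000628, adjusted p = 0.73 with an estimated correlation). Of the involution and acute phase genes 6 of 25 rose, among them the lysosomal proteases CTSD (1.32) and CTSB (1.02) and the acute phase regulator CEBPD (1.10), and 7 adjusted over the list alone (camera adjusted p = 0.000275, adjusted p = 0.73 with an estimated correlation). Of the immediate early and stress genes 6 of 22 rose and 2 fell, with JUND at 1.23, IER2 at 0.83, the heat shock gene HSPA1A at 1.04 and EGR3, above background on 1 of 4 arrays at day +120, at -1.74. Adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.00675, adjusted p = 0.73 with an estimated correlation). Cholesterol synthesis had 3 of 21 higher, TM7SF2 (3.21), FDFT1 (1.14) and PMVK (2.29), and 4 adjusted over the list alone (camera adjusted p = 0.000144, adjusted p = 0.73 with an estimated correlation). The record of the table called 757 genes, 462 of them in both and the same way, 110 higher and 352 lower (9.07 and 31.5 by chance), with 24 of 31 cell division genes and 2 of 14 endothelial markers. In it EGFL7, CLDN5, ENG, CEBPD, JUND, HSPA1A, EGR3, FDFT1 and PMVK did not pass. Without the 2 arrays low in milk protein mRNA 5863 genes passed, or 2669 by the table's record. With slide as a random block 958 genes passed and as a fixed block 0 (with RNASE3, EGR3 and the involution list turned, to 0.09, 0.57 and -0.22). Without animals 1, 2, 3 and 4 in turn 4524, 62, 437 and 157 did, the cholesterol synthesis call was lost with brightness as a covariate, the 8 arrays of both days alone gave 205, and 40.4% of the calls were higher, or 54.0% with normexp.

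At day +180, 1707 genes differed from day -30, 625 higher and 1082 lower. PTHLH was 4.12 ± 0.953 higher (SE, n = 4, adjusted p = 0.00748) and ENPP3, a nucleotide pyrophosphatase, 3.62 ± 0.814. ELP had a log2 change of -8.13 ± 0.975, RNASE3 of -6.85 ± 1.56, RSPO1 of -6.61 ± 1.02 and BCHE, butyrylcholinesterase, of -5.45 ± 0.925. At day +180 RNASE3, BCHE, DLGAP5 and KIF20A were above background on 2 of 4 arrays and EGR3 on 1. In cell division 23 of 32 fell (29 adjusted over the list alone), with a median of -2.72, DLGAP5 at -5.46, KIF20A at -3.65 and TPX2 at -2.31 (camera adjusted p = 1.8e-36, adjusted p = 0.38 with an estimated correlation). Of the interferon response genes 5 of 20 fell, also adjusted over the list alone, with IFIH1 at -0.97 and CXCL10 at -2.06 (camera adjusted p = 0.0113, adjusted p = 0.73 with an estimated correlation). Of the immediate early and stress genes 5 of 22 rose and 3 fell, with JUND at 1.30, IER2 at 0.89, the phosphatase DUSP1 at 1.69 and EGR3 at -1.54. Adjusted over the list alone 8 rose and 3 fell (camera adjusted p = 0.00366, adjusted p = 0.73 with an estimated correlation). Of the endothelial markers 1 of 14 rose, the tight junction gene CLDN5 (1.15), and 3 adjusted over the list alone (camera adjusted p = 0.0208, adjusted p = 0.748 with an estimated correlation). With brightness as a covariate the calls of the interferon and endothelial lists were lost. The table's record called 3511 genes, 1182 of them in both and the same way, 465 higher and 717 lower (41.4 and 98.8 by chance), with 24 of 31 cell division genes lower and 8 of 14 endothelial markers higher, and each gene named here among those in both. Without the 2 arrays low in milk protein mRNA 3858 genes passed. With slide as a random block 657 genes passed and as a fixed block 0 (with EGR3 and the endothelial list turned, to 0.23 and -0.29). Omitting animals 1, 2, 3 and 4 in turn gave 2703, 353, 564 and 271, the 8 arrays of both days alone 1118, and 36.6% of the calls were higher, or 49.0% with normexp.

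**Figure D3:**
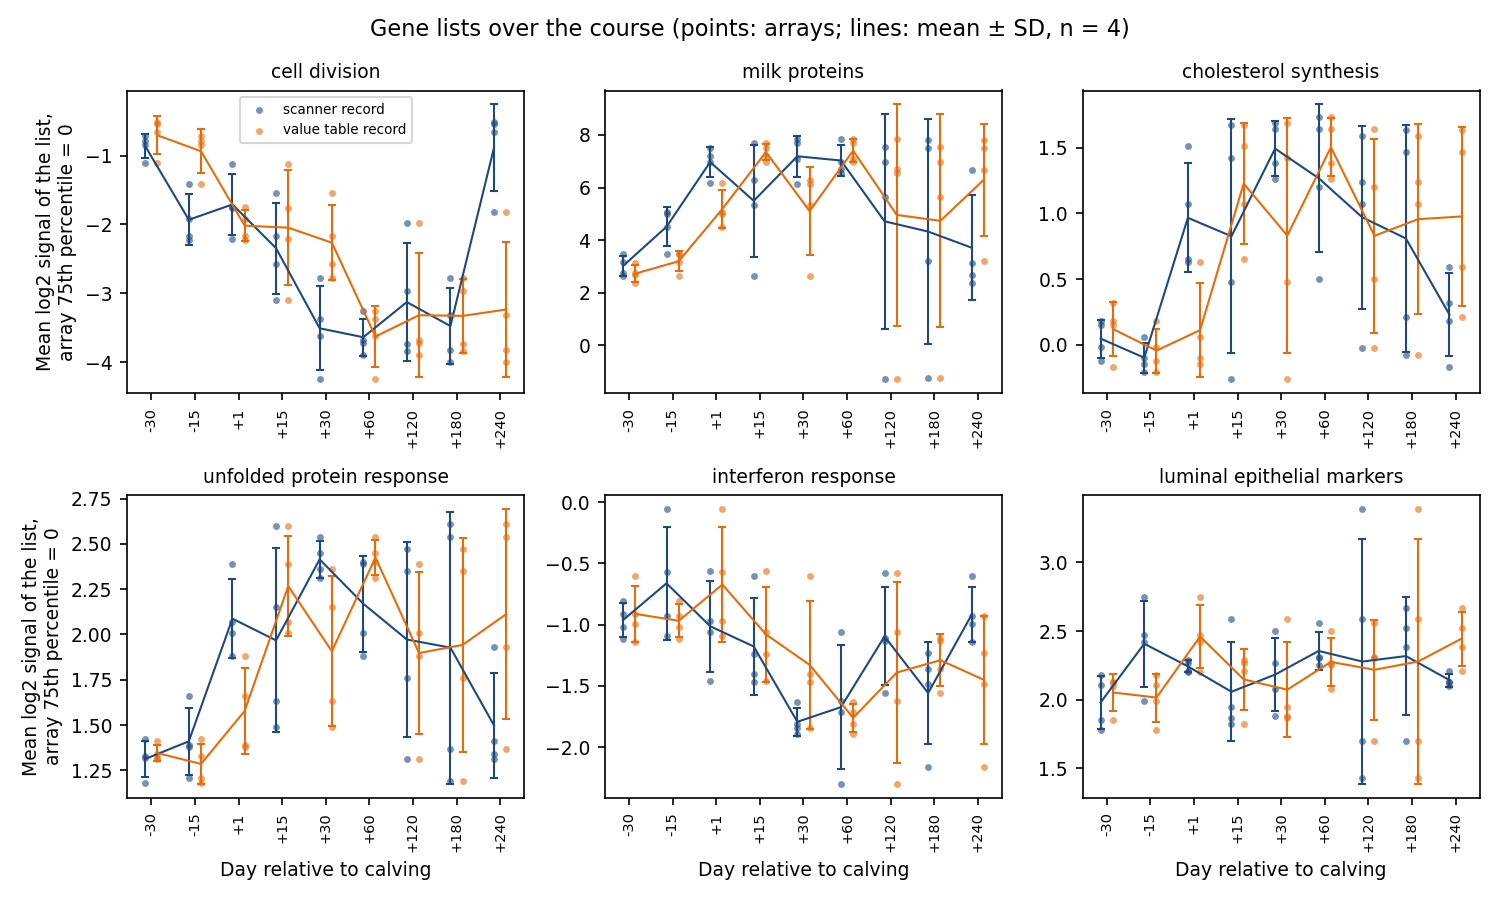
Mean log2 signal of 6 gene lists (vertical axes, 75th percentile of the array at 0) by day relative to calving (horizontal axes), for each array (points) and as mean ± SD of the 4 arrays of a day (lines), by the scanner record (blue) and the table's record (orange). Cell division returns at day +240 toward its level at day -30 by the scanner record and stays low by the table's record, where its median change from day +180 was 0.14.

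At day +240, 0 genes differed from day -30 with limma. An unadjusted p under 0.05 was reached by 318 genes, and by 423 in the ordinary linear model. Both counts are below the share of 0.05 of the 21559 genes tested that chance alone would give. The cell division list had a median change of -0.01 and 0 of 32 members passing. Involution and acute phase genes had a median change of 0.29 with 0 of 25 passing (camera adjusted p = 0.00233, adjusted p = 0.73 with an estimated correlation). LPL stood at 4.31 on the array of animal 1, which has this day in both records, and ELF5 at 5.04. On the other arrays of the day LPL lay between -0.1927 and -0.184 and ELF5 between 3.535 and 3.7. By the table's record these other arrays are of day -30, so that the lack of differences from day -30 depends on the record. By the table's record 2805 genes differed, 1380 higher and 1425 lower, and 0 were called in both. Without each animal in turn the count was 0 as well, and each of these fits kept arrays that the table gives as day -30.

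Day +240 differed from day +180 in 1002 genes, 702 higher and 300 lower. In cell division 21 of 32 rose (28 adjusted over the list alone), with a median of 2.54 (camera adjusted p = 6.17e-42, adjusted p = 0.38 with an estimated correlation). KIF20A was 3.87 ± 0.445 higher (SE, n = 4, adjusted p = 5.81e-06, in 4 of 4 animals), CCNB2 3.25 ± 0.428 and CDC20 3.05 ± 0.416. ELP was 8.46 ± 0.975, RNASE3 7.80 ± 1.56, the protease KLK6 5.61 ± 0.943 and RSPO1 5.05 ± 1.02 higher. At day +180 KIF20A and RNASE3 were above background on 2 of 4 arrays and KLK6 and EGR3 on 1. CYP1A1, a monooxygenase, had a log2 change of -4.96 ± 0.983, HPGD, which degrades prostaglandins, of -3.00, the chemokine GRO1 of -2.74, and SLC16A11, of the monocarboxylate transporter family, of -1.95. Of the immediate early and stress genes 4 of 22 fell, with DUSP1 at -1.66, JUND at -1.09 and IER2 at -0.85, and 1 rose, EGR3 at 1.40. Adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 0.000369, adjusted p = 0.73 with an estimated correlation). Of the endothelial markers 2 of 14 fell, CLDN5 (-1.25) and EGFL7 (-1.08), and 3 adjusted over the list alone (camera adjusted p = 0.00255, adjusted p = 0.73 with an estimated correlation). Of the interferon response genes 1 of 20 rose, DDX58 (0.87), and 4 adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.73 with an estimated correlation). The record of the table called 161 genes, 3 of them in both, all higher (4.13 higher and 0.237 lower by chance), and 0 of 31 cell division genes, whose median change was 0.14. None of the genes named here passed in it, where ELP had a change of 2.15, RNASE3 of 2.75, KLK6 of 1.74, RSPO1 of 0.39 and KIF20A of 0.31. There CYP1A1, HPGD and DUSP1 had changes of 0.21, 0.60 and 0.28 and the interferon list a median of -0.25. With slide as a random block 568 genes passed and as a fixed block 23 (with the endothelial list turned to 0.20). Leaving out animals 1, 2, 3 and 4 in turn gave 2628, 221, 229 and 99, brightness as a covariate 1869 (with the interferon call lost), the 8 arrays of both days alone gave 106, and 70.1% of the calls were higher, or 48.6% with quantile normalization.

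Between the other neighbouring days 0 or 1 gene passed in the fit to all arrays. From day -15 to day +1 the unnamed transcript TC461472 rose by 5.10 ± 0.84 (SE, adjusted p = 0.024), with 3217 genes at an unadjusted p under 0.05. Cholesterol synthesis had 0 of 21 members passing and 10 higher adjusted over the list alone (camera adjusted p = 9.92e-08, adjusted p = 0.73 with an estimated correlation). From day +1 to day +15 IGDCC4, a surface protein of the immunoglobulin family, was at least 1.26-fold higher (adjusted p = 0.0471), above background on 0 of 4 arrays at day +1. From day +60 to day +120 the olfactory receptor gene OR6C75 was at least 5.44-fold lower (adjusted p = 0.0267), above background on 0 of 4 arrays at day +120. These 3 genes are named because the counts were of 1 gene. In the remaining pairs 0 genes passed with limma: 1889 had an unadjusted p under 0.05 from day +15 to day +30 (1946 in the ordinary linear model), 1116 from day +30 to day +60 (1325) and 784 from day +120 to day +180 (915). Chance alone would give a share of 0.05 of the 21559 genes tested. The counts of 784 and 915 are below that share and 1116 lies near it. The table's record called 359, 64, 3, 177, 180 and 69 genes in these 6 pairs in order of time, none of them in both records. Without animal 1, 45 genes passed from day -15 to day +1, 10 from day +1 to day +15, 566 from day +15 to day +30 and 15 from day +30 to day +60. The 8 arrays of day -15 and day +1 alone gave 2371. Leaving out the 2 arrays low in milk protein mRNA gave 13 from day -15 to day +1, 7 from day +15 to day +30 and 30 from day +60 to day +120. A fixed block for slide gave 13, 15, 5, 119 and 54 in the 5 pairs from day +1 to day +180. The calls of all 3 named genes were lost with normexp, with slide as a random or a fixed block, without animal 2, 3 or 4 and by the table's record on scanner values, where IGDCC4 and OR6C75 turned (-0.23 and 0.70). Those of IGDCC4 and OR6C75 were also lost with brightness as a covariate, quantile normalization and the 8 arrays of both days alone, and those of TC461472 and OR6C75 in the ordinary linear model. IGDCC4 lost its call without the filter on dim probes, without a block and without the 2 arrays low in milk protein mRNA, and OR6C75 without animal 1 and with the mean of all probes. With quantile normalization another gene passed from day +60 to day +120, and it was higher.

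**Figure D4:**
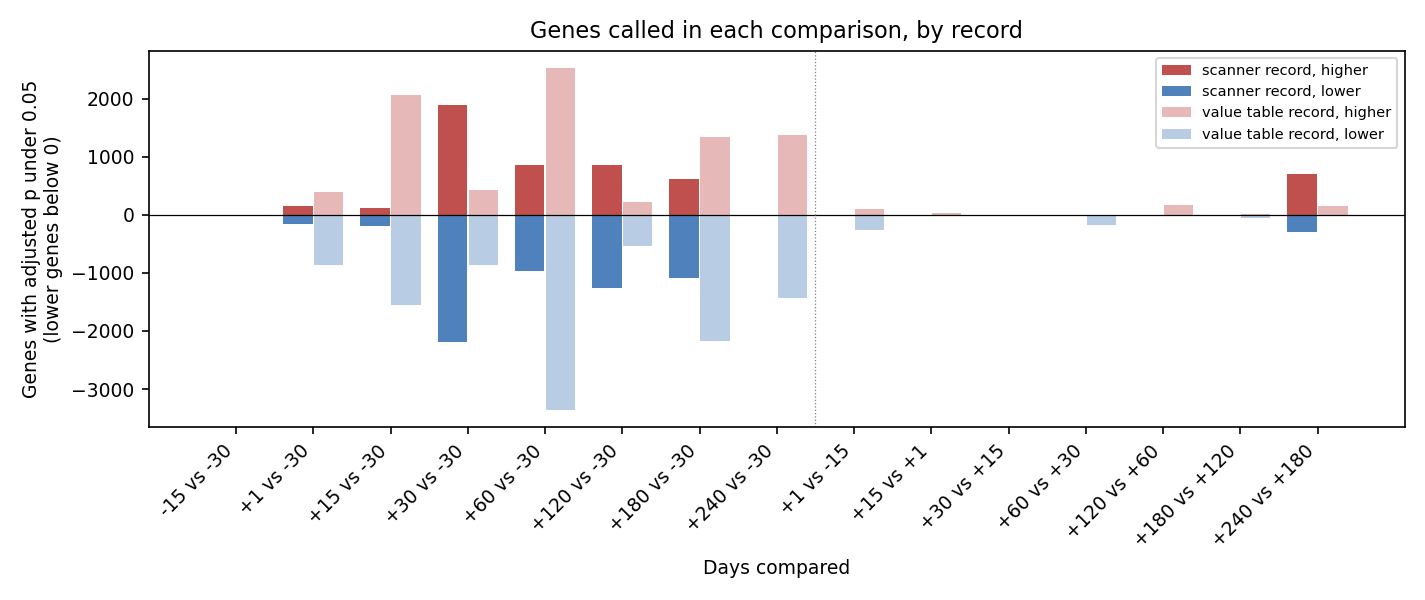
Genes higher (above 0) and lower (drawn below 0) with an adjusted p under 0.05 in each comparison of days, by the scanner record (dark bars) and by the table's record (light bars). At day +240 against day -30 the scanner record calls 0 genes and the table's record 2805.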

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

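The tests of explanations below, and the counts of splits of the arrays, were chosen or written down only after the results they concern had been seen.

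For 27 of the 36 arrays the table of normalized values gives another day than the scanner files. A candidate explanation is that 1 list was displaced by a few places when files and samples were joined: in slide order all 36 arrays differ between both records by the same 3 places, and in the table's record all 36 stand in the order of slides, days and animals, which the scanner record does for 0. This does not tell which record holds the true days. Of the 9 arrays with the same day in both, 6 correlated better with the 3 other arrays of their slide, which share their day in the table, and 3 with the arrays that share their day in the scanner files. Since the arrays of a slide may also resemble each other because they were processed together, the days of the table and the days of the scanner files cannot be told apart by this test.

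On 2 arrays of animal 1 (animal 4 in the table), at day +120 and day +180 in both records, milk protein genes were far below those of the other arrays (list means -1.3 and -1.23), and T and NK cell markers stood at -0.22 and -0.37, where the 3 other arrays of their day lay between -2.31 and -0.92. A weak signal of the array is argued against by the brightness of both, which lay above that of all 3 others of their day, by 1.05 and 0.166 on the log2 scale. This test replaced a first one, on the share of spots above background (7.92 and -4.78 percentage points from the highest of the others), after that one had left the question open. Less luminal epithelium in the tissue taken may be the source, but on only 1 of both arrays was the mean of the luminal markers below that of all 3 others. Involution in this animal on these days, the biological explanation, would raise the involution and acute phase list, whose mean difference from the others was -0.362, and with only 2 such arrays neither of these 2 explanations can be excluded.

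Cell division genes were lower at day +30 to day +180 than at day -30, in both records. With the brightness of the array as a covariate the list median nearest to 0 among these 4 comparisons was -1.71, at day +30, where the members called went from 29 to 11 (median -2.81 before). Standard errors there were 1.11 times those without the covariate, in the median over genes, while the genes called before had 0.425 times their change, and at day +120 and +180 23 and 22 members were still called, so that brightness is not the whole cause. Dilution by milk protein mRNA would lower all other genes alike, and the scaling of each array to its own percentile takes such a shift out. From day +30 to day +180 the median changes of all genes were -0.118, -0.0283, -0.0395 and -0.0154, far from those of the list. That argues against an even dilution as a cause of the fall of the list. Effects of dilution on members at the floor of the arrays were not tested. On the 2 arrays with little milk protein mRNA the list was also lower than in the same animal at day -30. Its median changes there were -0.799 and -1.57, with upper quartiles of -0.518 and -1.18. The list means of -1.98 and -2.78 on these arrays lay above the other arrays of these days (-3.99 to -2.96), for a reason that was not tested. A fixed block for slide gave list medians of -3.22, -3.1, -1.38 and -0.874 from day +30 to day +180 (-2.81, -3.01, -2.39 and -2.72 without it), with upper quartiles of -1.32, -1.57, -0.439 and -0.151. At day +120 and day +180 0 genes passed with that block, so that all calls of members were lost there. By the scanner record such a block compares days through animal 1 against animals 2 to 4 of the same slide. At day +120 and day +180 the arrays of animal 1 are the 2 low in milk protein mRNA. The medians stayed below 0, but they cannot tell slide from departures of animal 1. In the table slide and day are confounded, so that slide as a cause stays open. The stage of lactation stays open, untested.

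In 12 of 246 groups of 4 arrays, 1 array lay far from the 3 others by Dixon's ratio, which chance alone gives in about 1 of 20 groups. The 12 groups are about as many as chance alone would give, so that they do not mark these arrays as faulty. By the scanner record the 12 were LALBA at day -30 in animal 4 (0.8491 on the log2 scale) and PAEP in animal 1 at day -30 (4.593), both low, and those that follow. PAEP was also high in animal 3 at day +60 (8.427) and low in animal 1 at day +120 (1.046). LPL (4.312) and ELF5 (5.039) were high in animal 1 at day +240. FABP3 was low in animal 4 (0.6709) and THRSP high in animal 3 (1.98) at day -30. In animal 1, LTF (1.317) and KRT14 (0.8423) were low at day +15 and IGFBP5 (-0.9996) was high at day +1. The brightness of the array of animal 2 at day +30 was 2512, against 1278 to 1402 for the others.

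Other splits of the same arrays were tried for each count. Over the course, days were exchanged within each animal, and 1 of 100 such splits gave as many genes as the real one (4660, highest other 76), which argues against chance. These splits also part the arrays of a slide, so that they do not exclude slide (1322 genes with slide as a random block and 61 as a fixed block). At day +1, +15, +30, +60, +120 and +180 against day -30, 1 of 35 splits, the real one, gave as many genes (347, 313, 4074, 1821, 2122 and 1718 in a fit for the splits), with 0, 1, 1, 0, 1488 and 1 in the highest other. That would exclude chance for arrays without pairs, but the arrays are paired by animal. Only 8 of the 35 splits part all 4 pairs, too few for a share under 0.05, and in the highest other of these 0, 1, 0, 0, 0 and 0 genes passed. From day -15 to day +1 the real split gave 1 gene and the highest other 0, from which nothing is concluded, since that gene is lost in 10 of the alternatives, such as slide as a random block. At day -15 and day +240, from day +15 to day +30, from day +30 to day +60 and from day +120 to day +180 the real count was 0, which all 35 splits reach by construction, so that nothing follows from it (3, 1, 11, 11 and 6679 in the highest other). Chance was not excluded from day +1 to day +15 (3 of 35, 1 gene, highest other 1), from day +60 to day +120 (11 of 35, 1 gene, highest other 2538) and from day +180 to day +240 (2 of 35, 1001 genes, highest other 1512).

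Splits that call many genes point to a structure of the samples beside the day. From day +180 to day +240 the split with 1512 genes exchanges the arrays of animal 1, which puts the 4 arrays of 1 slide together, as the table's record does. It is 1 of 8 splits that part all 4 pairs, and the count with slide as a random block was 568. The split with 6679 genes from day +120 to day +180 puts both arrays low in milk protein mRNA in 1 group and parts fewer pairs. Among the 8 splits that part all pairs the highest other there was 1, and 0 at day +120 against day -30, where the split with 1488 parts fewer. From day +60 to day +120 the split with 2538 genes is 1 of the 8 that part all pairs, and it joins animals 1 and 3 at day +120 with animals 2 and 4 at day +60.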

How the results depend on the processing

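Alternatives chosen after seeing the data were the brightness of the array as a covariate, the table's record on scanner values and both fits without the 2 arrays low in milk protein mRNA. Of the 16 counts of genes, 134 values under alternatives were within 1.5 times the reported one and 169 were not. Of 48 list shifts, 797 values kept direction and call, 149 kept the direction only, 48 of them with an estimated correlation and 26 with the brightness covariate, and 14 reversed. For named genes these numbers were 2685, 1160 and 38, with 2 gaining a call. The settings in which most named genes lost their calls were slide as a fixed block (156), leaving out animals 4, 3 and 2 (137, 132 and 129) and the brightness covariate (109). In the F tests of 37 genes 584 kept their side of the threshold, 47 were lost and 35 gained. With the animal as a fixed effect all 16 counts were within 1.5 times. What made a count move was not tested, beyond the brightness covariate, under which changes became smaller (0.425 times at day +30 and 0.522 times at day +60, in the median over the genes called) and standard errors 1.11 and 1.08 times as large. Signal over background limits genes at the floor of the arrays.

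Counts moved as follows. With the table they were 8502 over the course, 1 at day -15, 1255 at day +1, 3609 at day +15, 1282 at day +30, 5889 at day +60, 757 at day +120, 3511 at day +180 and 2805 at day +240. Between neighbouring days the table gave 359, 64, 3, 177, 180, 69 and 161 in order of time. The table's record on scanner values gave 9122 over the course, 1, 1447, 3908, 1488, 6427, 992, 3872 and 3183 from day -15 to day +240, and 437, 78, 14, 231, 182, 57 and 161 between neighbouring days. The table without the 2 arrays gave 10227 over the course, 1, 1665, 4683, 1857 and 6855 from day -15 to day +60, 2669 at day +120, 5565 at day +180, 3974 at day +240, and 666, 400, 4, 379, 99, 73 and 81 between neighbouring days. The scanner record without the 2 arrays gave 7623 over the course, 1483 at day +1, 633 at day +15, 3235 at day +60, 5863 at day +120 and 3858 at day +180. It gave 13 from day -15 to day +1, 0 from day +1 to day +15, 7 from day +15 to day +30 and 30 from day +60 to day +120.

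The brightness covariate gave 0 at day +1, 121 at day +15, 271 at day +30 and 282 at day +60. It gave 0 from day +1 to day +15, 3 from day +15 to day +30, 0 from day +60 to day +120 and 1869 from day +180 to day +240.

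Slide as a random block gave 1322 over the course, 0 at day +1, 7 at day +15, 2033 at day +30, 1076 at day +60, 958 at day +120 and 657 at day +180. It gave 0 from day -15 to day +1, from day +1 to day +15 and from day +60 to day +120, and 568 from day +180 to day +240. Slide as a fixed block gave 61 over the course, 0 at day +1, 4 at day +15, 500 at day +30, and 0 at day +120 and day +180. Between neighbouring days it gave 0, 13, 15, 5, 119, 54 and 23.

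The normexp correction gave 1844 over the course, 106 at day +1, 105 at day +15, 6534 at day +30, 944 at day +60, 911 at day +120 and 588 at day +180. It gave 0 from day -15 to day +1, from day +1 to day +15 and from day +60 to day +120, and 236 from day +180 to day +240. Quantile normalization gave 482 at day +1, 531 at day +15, 2 from day -15 to day +1, 0 from day +1 to day +15 and 1 from day +120 to day +180. The 8 arrays of the compared days alone gave 71, 7416, 675, 7415, 2792, 205 and 1118 from day -15 to day +180, 2371 from day -15 to day +1, 0 from day +1 to day +15 and from day +60 to day +120, and 106 from day +180 to day +240. No filter on dim probes gave 3269 at day +60, 3432 at day +120 and 0 from day +1 to day +15. The ordinary ANOVA gave 130 at day +1 and 0 from day -15 to day +1 and from day +60 to day +120. The mean of all probes gave 8 from day -15 to day +1 and 0 from day +60 to day +120, and no block gave 0 from day +1 to day +15.

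Without each animal in turn the counts ran from 506 to 6780 over the course, 0 to 209 at day -15, 0 to 883 at day +1, 0 to 234 at day +15, 550 to 3732 at day +30, 385 to 1431 at day +60, 62 to 4524 at day +120 and 271 to 2703 at day +180. Between neighbouring days they ran from 0 to 45, 0 to 10, 0 to 566, 0 to 15, 0 to 4, 0 to 2 and 99 to 2628 in order of time. The upper end was each time the count without animal 1, where each day lies on 1 slide of its own. Of the 450 list tests 152 passed and 0 did with an estimated correlation.

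Reversed directions had causes that were not tested. Under quantile normalization the ribosomal protein list at day +30 had a median of -0.125. Under the brightness covariate CSN1S2 (-0.1044), XDH (-0.1967), SCD (-0.0194) and ELF5 (-0.3173) turned at day +30, and triacylglycerol synthesis and milk fat globule (-0.251) at day +60. With slide as a fixed block the lists of involution at day +120 (-0.219), endothelial markers at day +180 (-0.291) and from day +180 to day +240 (0.2), mucosal defence (-0.325) and, by the test alone, neutrophil markers (median 0.207) at day +15 turned. So did ATP2B2 (-0.3674), RRAD (-0.9455), GALNTL2 (-1.64) and EGR3 (0.2315) at day +180, RNASE3 (0.0911), EGR3 (0.5653) and DUSP9 (0.8225) at day +120, MCM7 (0.1094), DUSP9 (0.5842) and CHRDL2 (1.028) at day +1, and CHRDL2 at day +15 (0.7473) and day +30 (1.072). With the table the myoepithelial list at day -15 (-0.005) turned, and from day +180 to day +240 CCNB1 (-0.1085), KIAA0101 (-0.2132), BCHE (-0.3765), CYP1A1 (0.2113), DUSP1 (0.2786), HPSE (0.4206), HPGD (0.6039) and the lists of interferon response (-0.246) and, by the test, cell division (median 0.144). On scanner values these were -0.0767, -0.1077, -0.2124, -0.3757, 0.2121, 0.2793, 0.4214, 0.6047, -0.246 and 0.117, and IGDCC4 from day +1 to day +15 (-0.2278) and OR6C75 from day +60 to day +120 (0.6976) turned. In the table without the 2 arrays, interferon response (-0.34), HPSE (0.0847), SLC26A10 (0.1379), TNFAIP6 (0.1831), DUSP1 (0.2311), CYP1A1 (0.247) and HPGD (0.4142) did so from day +180 to day +240.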

Other observations

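Lists of other cell types moved on the arrays of animal 1 that were low in milk protein mRNA. B and plasma cell markers had means of -1.71 at day +120 and -0.86 at day +180, where the 3 other arrays lay between -3.63 and -2.43 at both days, and cell division genes stood at -1.98 and -2.78 against -3.99 to -2.96. No test was run on these differences.

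The closest pair of the 36 arrays was animal 4 at day -30 and at day +240 of the scanner record (r = 0.989 across genes, which are not independent replicates), which the table gives as day -15 and day -30.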
